A study of Homo sapiens with 24 samples.

How the data were processed

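Total RNA from 4 established head and neck squamous cell carcinoma lines was labelled with biotin as cRNA and hybridised to Illumina beadchips, per the labels' protocols. Each line was measured as an erlotinib-sensitive parental culture and as an erlotinib-resistant culture, with 3 arrays in each of the 8 groups and 24 arrays in all. Groups and replicate numbers were taken from the sample titles.

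The probe-level intensity values deposited by the authors are mean bead signals on a linear scale, without background subtraction and without normalization between arrays, as the values themselves show. They came in 2 tables of 12 arrays, 1 with SCC-25 and Cal-27 and 1 with FaDu and SQ20B. Beside each intensity the authors deposited a detection p-value, the share of negative control beads at least as bright as the probe, in steps set by 770 control beads. The number of beads behind each intensity was also deposited by the authors. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. A further table deposited by the authors holds processed intensity values of the same arrays, and how they were processed is not given in the sources used here. Those values are linear, with a median per array of 8.60 to 8.63 for SCC-25 and Cal-27 and of 7.26 to 7.30 for FaDu and SQ20B. A median of 28.3% and 28.4% of the values per array were negative in the 2 sets, as background subtraction gives. Within a set the sorted values of any 2 arrays differed by at most 1.26 and 1.37 intensity units, as quantile normalization of each set gives. Each processed column had a rank correlation of 1 with the bead signals of its own array.

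Background was corrected with neqc in limma 3.58.1 under R 4.3.3, which fits a normal and exponential mixture from the detection p-values and adds an offset of 16. Quantile normalization and log2 followed, separately within each table of 12 arrays. All tests were run within a table, and a level of SCC-25 or Cal-27 is on another scale than a level of FaDu or SQ20B. Of the 47231 probes, 30113 had 1 gene symbol in the platform annotation, 8 had several and 17110 are not listed there and are unnamed here. Symbols were checked through the Entrez identifier for 30074 probes against the RefSeq gene table of GRCh38.p14, and 0 changed. That table was used for names only, and no coordinates are printed because the files name no genome build. A probe was tested when its detection p was under 0.05 on at least 3 of the 24 arrays and it had 1 symbol. For each gene the brightest such probe was kept, which left 14077 genes, 3934 of them with more than 1 tested probe. No column belonged to a sample outside the series.

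Resistant and sensitive cells of each line were compared with lmFit and eBayes in limma, with the 4 groups of a table in 1 fit that leaves 8 residual degrees of freedom. The 2 differences between lines of the same table were tested as interactions in the same fit. Values are written as the log2 change, resistant minus sensitive, ± its standard error from limma, with 3 arrays on each side. Adjusted p is limma's p after Benjamini-Hochberg adjustment over the 14077 genes, and a gene was called when it was under 0.05. A second count asked in addition for at least a 2-fold change. The mean change over the 4 lines was tested with limma on the 4 changes. A gene with a detection p of 0.05 or more on all 3 arrays of a group has only a bound there. Its fold is written as "at least", the brighter group's mean against the higher of the dim probe's own signal and the lowest detected signal on each array.

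Before the data were examined, 23 gene lists were fixed, with 604 entries of which 488 were measured. They are EGFR family and ligands, other receptor tyrosine kinases and ligands, ERK pathway output, IL-6 family and JAK-STAT3, IL-1 family and MyD88 signalling, NF-kB target cytokines and regulators, type I interferon response, and antigen presentation. The next are mesenchymal genes, epithelial adhesion, squamous differentiation, basal keratinocyte, NRF2 targets, drug metabolism and efflux, NADPH oxidases, cell cycle, and hypoxia and glycolysis. The last are cholesterol synthesis, ATF4 and unfolded protein response, BCL2 family, YAP and TGF-beta targets, heat shock, and leukocyte, endothelial and melanocyte markers. The IL-6 and IL-1 lists were chosen with knowledge of published work on these cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists of a line, and again with the correlation estimated from the data.

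The rule for named genes was fixed at the same time. It took, per line, the 8 highest and 8 lowest changes among called genes whose 3 resistant arrays all lay above or all below the 3 sensitive arrays. It also took up to 2 called members per list and direction, and the 10 genes with the largest mean change in each direction among those called alike in all 4 lines. For each table it took the 5 genes with the largest interaction among those called in opposite directions. EGFR, ERBB2, ERBB3, MET, AXL, IL6, IL1A and IL1B were taken whatever their call.

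Alternatives were no background correction, normexp with an offset of 50, median scaling, all 24 arrays normalized together, the processed values, a detection p under 0.01, no detection filter, and the mean of a gene's probes. Further ones were only the arrays of the line, eBayes with trend, the replicate number as a block, an estimated correlation in camera, and each array left out in turn. For genes shared by the lines, a 2-fold change in each line and each line left out were tried, and for pairs of lines, genes detected on every array. No alternative was added after the data were examined. The slide as a block was not run, because the columns name no slide.

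The procedure was tested on simulated arrays with the real means and spreads and 200 changed genes. A log2 change of 1 was recovered for 91.0% of genes in SCC-25, 94.0% in Cal-27, 95.5% in FaDu and 89.6% in SQ20B. For a change of 0.5 the shares were 53.7%, 34.3%, 55.2% and 52.2%. Unchanged genes made up 4.68%, 3.80%, 5.14% and 5.29% of the simulated calls. In the real comparisons 30.9% to 54.3% of genes were called, so the adjusted threshold was stricter in the simulation. The simulated genes also varied independently of each other. These shares are therefore not the sensitivity of the real comparisons. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

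Mean intensity per array lay between 329 and 458, and 39.5% to 45.0% of probes were detected. The mean number of beads per probe was 19.6 to 21.5. With arrays, their number limits the precision. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.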

Results

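Gene expression was measured in erlotinib-sensitive and erlotinib-resistant cells of 4 head and neck squamous cell carcinoma lines. SCC-25 and Cal-27 derive from the tongue, FaDu from the pharynx and SQ20B from the larynx. Erlotinib inhibits the tyrosine kinase of the epidermal growth factor receptor, EGFR. All cultures received 0.01% DMSO, the vehicle, for 48 h before RNA was taken, and resistant cells were kept in medium with erlotinib. Whether erlotinib was still present in those 48 h is not given in the sources used here. Each of the 8 groups had 3 arrays, and replicates of a group correlated at 0.991 to 0.996 across genes, which are not independent replicates. Each resistant culture correlated best with the sensitive culture of its own line, at 0.981 in SCC-25, 0.974 in Cal-27, 0.971 in FaDu and 0.943 in SQ20B. The comparisons ask which genes differ between resistant and parental cells, and whether the lines changed alike. The labels name no separately derived resistant cultures of a line. Resistance therefore cannot be told apart from other differences between a line's resistant and parental cultures.

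IL6, which encodes the cytokine interleukin-6, was higher in resistant cells of all 4 lines. Its probe, ILMN_1699651, rose by 1.24 ± 0.17 on the log2 scale in SCC-25, 2.30 ± 0.17 in Cal-27, 2.49 ± 0.14 in FaDu and 2.74 ± 0.14 in SQ20B. Adjusted p from limma was 0.000167, 5.59e-07, 4.35e-08 and 7.28e-09. In sensitive FaDu cells IL6 lay at 4.98 to 5.34, near background, so the size of its rise there depends on the background correction. IL6 belongs to a list chosen with knowledge of published work on these cells, so its rise is not independent evidence.

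The interleukin-1 genes split the lines. IL1A rose by 3.08 ± 0.17 in Cal-27 and 3.20 ± 0.14 in SQ20B, fell by 1.03 ± 0.17 in SCC-25, and stood at -0.12 ± 0.14 in FaDu (adjusted p = 0.539). IL1B rose by 1.53 ± 0.15 in Cal-27 and 1.69 ± 0.11 in SQ20B and fell by 1.11 ± 0.15 in SCC-25 and 0.96 ± 0.11 in FaDu. The difference between SCC-25 and Cal-27 was called for IL1A (adjusted p = 6.69e-08) and IL1B (adjusted p = 1.66e-06). Between FaDu and SQ20B it was also called for both, with adjusted p = 7.51e-08 and 5.28e-08.

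EGFR, the target of the drug, did not fall on its brightest probe, ILMN_1798975. That probe rose by 0.41 ± 0.08 in SCC-25 and by 0.96 ± 0.08 in both FaDu and SQ20B, and stood at -0.06 ± 0.08 in Cal-27 (adjusted p = 0.634). The probes of EGFR disagreed, and the mean of its probes turned the SCC-25 value to -0.22, still called. A dimmer EGFR probe, ILMN_1728858, fell by 1.27 ± 0.10 in SCC-25 and by 0.65 ± 0.10 in Cal-27. Another, ILMN_1696521, rose by 0.32 ± 0.10 in Cal-27, 0.70 ± 0.12 in FaDu and 0.63 ± 0.12 in SQ20B, and stood at -0.05 ± 0.10 in SCC-25. ERBB2, another receptor of the family, rose by 0.61 ± 0.10 in SCC-25, 0.53 ± 0.09 in FaDu and 0.47 ± 0.09 in SQ20B. In Cal-27, ERBB2 stood at 0.08 ± 0.10, MET at 0.20 ± 0.13 and AXL at 0.12 ± 0.12, none of them called (adjusted p = 0.606, 0.28 and 0.529). ERBB3 rose in all 4 lines on its brightest probe, most in FaDu at 1.19 ± 0.12. Of 17 alternatives, 4 did not call it in Cal-27 and 1 did not in SQ20B. With the mean of its probes ERBB3 stood at -0.12 in Cal-27 and -0.11 in SQ20B, neither called. A dimmer ERBB3 probe, ILMN_1737993, fell by 0.57 ± 0.12 in Cal-27 and fell by 0.54 ± 0.16 in SQ20B. MET, the hepatocyte growth factor receptor, rose by 0.95 ± 0.09 in FaDu and fell by 0.73 ± 0.13 in SCC-25. In SQ20B, MET was called at 0.33 ± 0.09 and stood at 0.16 with median scaling, where its call ended. AXL, a receptor tyrosine kinase, rose by 0.86 ± 0.12 in SCC-25 and 0.58 ± 0.11 in FaDu. AXL in SQ20B was called at 0.29 ± 0.11 and lost its call under 9 of 17 alternatives.

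**Figure D1:**
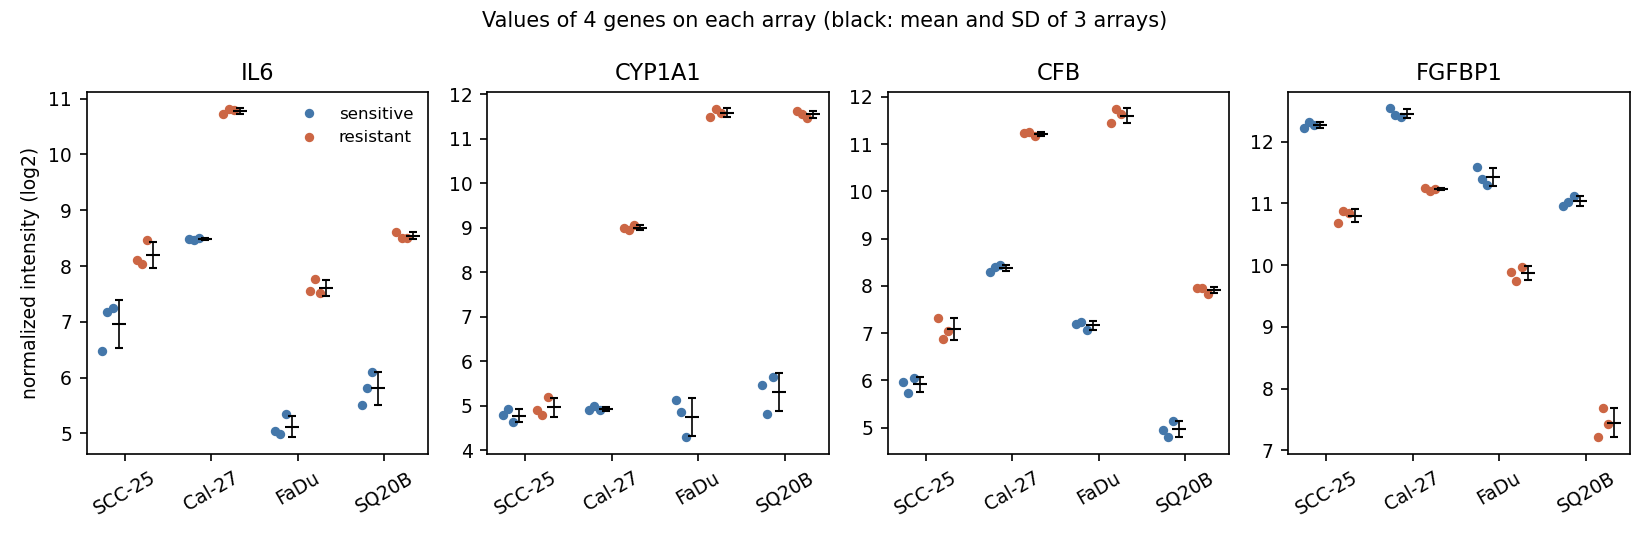
Normalized log2 intensity of IL6, CYP1A1, CFB and FGFBP1 (vertical axes) on each array by cell line, with sensitive cells in blue, resistant cells in orange, and the mean and SD of 3 arrays in black. IL6 and CFB are higher and FGFBP1 is lower in the resistant cells of all 4 lines, CYP1A1 is higher in all lines but SCC-25, and levels of SCC-25 and Cal-27 are on another scale than those of FaDu and SQ20B.

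In SCC-25, resistant cells had less transcript of amino acid and stress response genes, of hypoxia and glycolysis genes and of ERK-responsive genes. They had more of cell cycle genes. None of these lists kept its call with an estimated correlation (adjusted p = 0.342, 0.288, 0.288 and 0.342). The largest rises were those of FOLR1, a folate receptor, at 4.33 ± 0.11, DCN, which encodes the matrix proteoglycan decorin, at 4.15 ± 0.10, and PLAC8 at 4.01 ± 0.13. NNMT, nicotinamide N-methyltransferase, rose by 3.39 ± 0.17 and CADM1, a cell adhesion molecule, by 3.31 ± 0.09. The lowest changes were those of LGALS7B at -3.56 ± 0.11 and LGALS7 at -3.31 ± 0.18, near-identical genes of a keratinocyte galectin whose probes may read both. The gap junction genes GJB6 and GJB2 fell by 3.29 ± 0.15 and 3.25 ± 0.14, and PLAU, the urokinase gene, fell by 3.14 ± 0.09. MMP9, a gelatinase, was at least 6.3-fold lower, with adjusted p = 3.86e-07.

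Of 26 measured ATF4 and unfolded protein response genes in SCC-25, 14 fell, 2 rose and 10 were not called (camera adjusted p = 0.000667, adjusted p = 0.342 with an estimated correlation). ASNS, asparagine synthetase, fell by 2.31 ± 0.22 and TRIB3 by 1.38 ± 0.14. Of 25 hypoxia and glycolysis genes, 11 fell and 1 rose, with 12 and 1 adjusted over the list alone (camera adjusted p = 0.00199, adjusted p = 0.288 with an estimated correlation). CA12, a carbonic anhydrase, fell by 2.05 ± 0.15, while HK2, a hexokinase, rose by 1.03 ± 0.11. Of 23 ERK pathway output genes, 11 fell and 2 rose, with 12 and 2 adjusted over the list alone (camera adjusted p = 0.00347, adjusted p = 0.288 with an estimated correlation). ETV4 fell by 1.47 ± 0.10 and HMGA2 by 1.16 ± 0.10. Among 15 basal keratinocyte genes 8 fell, PDPN by 0.87 ± 0.10 and COL7A1 by 0.86 ± 0.14, and 1 rose, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.00393, adjusted p = 0.288 with an estimated correlation). Among 15 heat shock genes 9 fell and 0 rose, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.00489, adjusted p = 0.288 with an estimated correlation). CRYAB fell by 0.72 ± 0.08. Cell cycle genes went the other way, with 14 of 36 higher and 1 lower, and 16 and 1 adjusted over the list alone (camera adjusted p = 0.00393, adjusted p = 0.342 with an estimated correlation). CENPF rose by 0.96 ± 0.10 and KIF11, a mitotic kinesin, by 0.64 ± 0.09.

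Epithelial adhesion genes in SCC-25 fell in 13 of 26 cases, ST14 by 1.18 ± 0.10, and rose in 6, CLDN1 by 1.51 ± 0.12, with 14 and 6 adjusted over the list alone (camera adjusted p = 0.0499, adjusted p = 0.342 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 19 cases, INSIG1 by 0.89 ± 0.15, and rose in 1 (camera adjusted p = 0.0452, adjusted p = 0.421 with an estimated correlation). These 2 list calls were lost under 5 and 3 of 11 other settings, and with 4 and 3 of the 6 arrays left out in turn. In all, 4348 of 14077 genes were called in SCC-25, 2164 higher and 2184 lower, and 558 changed at least 2-fold, 293 higher and 265 lower. No list of the 8 called in SCC-25 kept its call with an estimated correlation. Among lists not called in SCC-25, 8 interferon-response genes of 34 rose and 2 fell (camera adjusted p = 0.0738), and 7 NF-kB targets of 27 rose and 5 fell (camera adjusted p = 0.528). Without background correction 185 genes changed at least 2-fold, and 268 with normexp and an offset of 50.

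In Cal-27, resistant cells had more transcript of NF-kB targets and antigen presentation genes and less of interferon-response genes. GDF15, a stress-responsive cytokine, rose by 6.37 ± 0.14, and the chemokine genes CCL2 and CCL20 by 5.94 ± 0.12 and 4.94 ± 0.15. ALOX5AP, which serves leukotriene synthesis, was at least 15.0-fold higher (adjusted p = 4.38e-10). CYP1A1, a cytochrome P450 gene induced through the aryl hydrocarbon receptor, rose by 4.07 ± 0.11, and by 2.32 without background correction, as its level in sensitive cells was near background. KRT14, a basal keratin, fell by 6.24 ± 0.12, the cornified envelope gene SPRR1A by 4.64 ± 0.46, the desmosomal gene PKP1 by 4.34 ± 0.13 and CD24 by 4.39 ± 0.24. TEAD2 was at least 16-fold lower and KRT13 at least 9.46-fold lower.

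NF-kB targets rose in 21 of 27 cases and fell in 1 in Cal-27 (camera adjusted p = 3.99e-16). Of 26 ATF4 and unfolded protein response genes, 22 rose, NUPR1 by 2.94 ± 0.32 and STC2 by 2.67 ± 0.17, and 1 fell (camera adjusted p = 1.19e-12, adjusted p = 0.0628 with an estimated correlation). Antigen presentation genes rose in 14 of 19 cases and fell in 0, with HLA-DMB at 2.66 ± 0.17 and HLA-DMA at 2.47 ± 0.11, which load peptides on class II molecules (camera adjusted p = 4.81e-10). Interferon-response genes fell in 22 of 34 cases and rose in 5, with 23 and 5 adjusted over the list alone (camera adjusted p = 3.26e-08). OASL fell by 3.95 ± 0.16 and RSAD2 was at least 8.09-fold lower, while IFITM1 rose by 0.89 ± 0.14. Squamous differentiation genes fell in 20 of 29 cases and rose in 1 (camera adjusted p = 2.86e-08, adjusted p = 0.0653 with an estimated correlation). Basal keratinocyte genes fell in 10 of 15 cases, KRT16 by 3.72 ± 0.16, and rose in 3, PDPN by 0.75 ± 0.10 (camera adjusted p = 0.000285, adjusted p = 0.0628 with an estimated correlation).

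Cell cycle genes fell in 24 of 36 cases in Cal-27 and rose in 0, with 26 and 0 adjusted over the list alone (camera adjusted p = 3.05e-07, adjusted p = 0.0755 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 0.78 ± 0.12 and AURKB by 0.73 ± 0.10. Cholesterol synthesis genes rose in 12 of 19 cases, SC5D by 1.55 ± 0.12, and fell in 1, with 14 and 1 adjusted over the list alone (camera adjusted p = 5.38e-05, adjusted p = 0.0777 with an estimated correlation). Heat shock genes fell in 11 of 15 cases, HSPA1A by 0.79 ± 0.09, while HSPB8 rose by 2.67 ± 0.12 (camera adjusted p = 0.000337, adjusted p = 0.0777 with an estimated correlation). The IL-6 family and JAK-STAT3 list, which is not independent evidence, rose in 9 of 15 cases and fell in 1 (camera adjusted p = 0.000924). LIF, a cytokine of that family, rose by 1.40 ± 0.20. ERK pathway output genes rose in 12 of 23 cases, ETV5 by 2.48 ± 0.10, and fell in 3, EGR1 by 2.63 ± 0.23, with 13 and 3 adjusted over the list alone (camera adjusted p = 0.0020, adjusted p = 0.173 with an estimated correlation). YAP and TGF-beta targets fell in 10 of 24 cases, ID3 by 1.91 ± 0.14, and rose in 4, ANKRD1 by 1.62 ± 0.16, with 11 and 4 adjusted over the list alone (camera adjusted p = 0.0214, adjusted p = 0.0653 with an estimated correlation). CDH5, an endothelial cadherin on the list of markers of other cell types, rose by 3.56 ± 0.10, while that list was not called in Cal-27 (camera adjusted p = 0.507).

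In all, 4765 genes were called in Cal-27, 2311 higher and 2454 lower, and 802 changed at least 2-fold, 461 higher and 341 lower. Of the 12 lists called, NF-kB targets (adjusted p = 0.00823), interferon response (0.00823), antigen presentation (0.0251) and the IL-6 list (0.031) kept their calls with an estimated correlation. Without background correction 317 genes changed at least 2-fold, and 437 with normexp and an offset of 50.

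In FaDu, resistant cells had more transcript of NF-kB target and interferon-response genes. They had less of cholesterol synthesis genes and of hypoxia and glycolysis genes. CYP1A1 rose by 6.83 ± 0.21 in FaDu and CYP1B1, another aryl hydrocarbon receptor target, by 4.37 ± 0.12. CYP1A1 was near background in sensitive cells, and without background correction its rise was 4.84 in FaDu and 4.60 in SQ20B. IGFBP5, an insulin-like growth factor binding protein, rose by 5.99 ± 0.17, LCN2, a secreted iron-siderophore binding protein, by 5.17 ± 0.12, and RARRES1 by 5.13 ± 0.11. CFB, complement factor B, rose by 4.44 ± 0.11. The protease genes KLK6 and MMP13 fell by 3.45 ± 0.09 and 2.67 ± 0.15, DPYSL3 by 2.73 ± 0.16 and KRT14 by 2.37 ± 0.11. ANGPTL4 was at least 4.64-fold lower and IL24 at least 4.55-fold lower.

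NF-kB targets rose in 18 of 27 cases in FaDu and fell in 0 (camera adjusted p = 1.3e-07). Interferon-response genes rose in 21 of 34 cases and fell in 6, with 22 and 8 adjusted over the list alone (camera adjusted p = 7.42e-06). IFI27 rose by 4.13 ± 0.10 and OAS2, an RNA sensor, by 3.12 ± 0.09, while OASL fell by 1.40 ± 0.12. Antigen presentation genes rose in 15 of 19 cases and fell in 0, with HLA-B at 2.28 ± 0.09 and HLA-F at 1.29 ± 0.12, class I genes whose sequences are alike (camera adjusted p = 6.11e-06). Cholesterol synthesis genes fell in 15 of 19 cases, MVK by 1.33 ± 0.13 and ACAT2 by 1.08 ± 0.09, and rose in 2, with 16 and 2 adjusted over the list alone (camera adjusted p = 1.2e-05). Hypoxia and glycolysis genes fell in 16 of 25 cases, NDRG1 by 1.55 ± 0.11, and rose in 2, ADM by 2.00 ± 0.11 (camera adjusted p = 3.22e-05).

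Cell cycle genes fell in 22 of 36 cases in FaDu, MCM5 by 0.87 ± 0.09, and rose in 3, CENPF by 0.63 ± 0.12, with 22 and 5 adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.0865 with an estimated correlation). YAP and TGF-beta targets rose in 10 of 24 cases, NT5E by 3.90 ± 0.08 and CCN2 by 3.69 ± 0.12, and fell in 4, ID1 by 1.08 ± 0.07 (camera adjusted p = 0.00388, adjusted p = 0.116 with an estimated correlation). Heat shock genes fell in 7 of 15 cases, HSP90AB1 by 0.64 ± 0.09, and rose in 1, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.021, adjusted p = 0.188 with an estimated correlation). Drug metabolism and efflux genes rose in 7 of 20 cases and fell in 3, CYP4F11 by 1.50 ± 0.14 (camera adjusted p = 0.0325, adjusted p = 0.0865 with an estimated correlation). CDH5 rose by 2.56 ± 0.14 and VWF, another endothelial gene, fell by 1.03 ± 0.12, and their list was not called (camera adjusted p = 0.723).

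In all, 5762 genes were called in FaDu, 2900 higher and 2862 lower. Those with at least a 2-fold change numbered 813, of which 625 were higher and 188 lower. Of the 9 lists called, 5 kept their calls with an estimated correlation, at adjusted p = 0.00467 for NF-kB targets, interferon response and antigen presentation and 0.0157 for cholesterol synthesis and for hypoxia and glycolysis. Without background correction 299 genes changed at least 2-fold, and 404 with normexp and an offset of 50.

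In SQ20B, interferon-response genes made up much of the upper end of the changes, and cell cycle and cholesterol synthesis genes were lower in resistant cells. IFI27 was at least 180-fold higher and IFI44L at least 73.5-fold higher, both with adjusted p = 2.8e-14. OAS2 rose by 6.25 ± 0.09 and MX1, an antiviral GTPase, by 5.80 ± 0.10. CYP1A1 rose by 6.24 ± 0.21, DHRS2 by 5.68 ± 0.17 and LAMP3 by 5.56 ± 0.16. GAL, the neuropeptide galanin, fell by 3.99 ± 0.08, and the lowest changes also held the growth factor carrier FGFBP1 at -3.59 ± 0.12 and CA2, a carbonic anhydrase, at -3.38 ± 0.15. SOX2, a transcription factor of stem and basal cells, was at least 9.66-fold lower.

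Of 34 interferon-response genes in SQ20B, 33 rose and 0 fell, with 34 and 0 adjusted over the list alone (camera adjusted p = 8.52e-25). Cell cycle genes fell in 35 of 36 cases and rose in 0 (camera adjusted p = 3.67e-16). RRM2 fell by 2.10 ± 0.13 and MCM5, part of the replicative helicase, by 2.03 ± 0.09. Cholesterol synthesis genes fell in 15 of 19 cases, MVD by 2.31 ± 0.13 and INSIG1 by 2.20 ± 0.08, and rose in 1 (camera adjusted p = 3.32e-08). ATF4 and unfolded protein response genes rose in 21 of 26 cases, ATF3 by 3.06 ± 0.11, and fell in 3 (camera adjusted p = 2.33e-06). The endoplasmic reticulum genes CRELD2 and SDF2L1 were among those 3 and fell by 1.11 ± 0.10 and 1.08 ± 0.07. Antigen presentation genes rose in 12 of 19 cases and fell in 0, with HLA-B at 4.06 ± 0.09 and HLA-F at 3.84 ± 0.12 (camera adjusted p = 7.55e-06).

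Heat shock genes fell in 11 of 15 cases in SQ20B, HSPA8 by 1.80 ± 0.09, while HSPB8 rose by 1.91 ± 0.12 (camera adjusted p = 0.000352, adjusted p = 0.0656 with an estimated correlation). Mesenchymal genes rose in 11 of 23 cases and fell in 0 (camera adjusted p = 0.000762). LUM, a matrix proteoglycan, was at least 24-fold higher and COL5A1 rose by 4.11 ± 0.13. YAP and TGF-beta targets rose in 15 of 24 cases, CCN2 by 3.99 ± 0.12 and EDN1 by 3.68 ± 0.14, and fell in 4 (camera adjusted p = 0.00686, adjusted p = 0.132 with an estimated correlation). Drug metabolism and efflux genes rose in 11 of 20 cases, GSTM1 by 3.68 ± 0.10, and fell in 3, with the efflux pump ABCG2 at -1.60 ± 0.09 (camera adjusted p = 0.0129, adjusted p = 0.0513 with an estimated correlation).

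In all, 7640 genes were called in SQ20B, 4002 higher and 3638 lower, and 1972 changed at least 2-fold, 1195 higher and 777 lower. Of the 9 lists called, 6 kept their calls with an estimated correlation. Adjusted p was then 4.29e-05 for interferon response, 0.00237 for cell cycle, 0.00374 for cholesterol synthesis, ATF4 and antigen presentation, and 0.0138 for mesenchymal genes. NF-kB targets, with 9 of 27 higher and 7 lower, were not called in SQ20B (camera adjusted p = 0.596). Without background correction 910 genes changed at least 2-fold, and 1176 with normexp and an offset of 50.

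**Figure D2:**
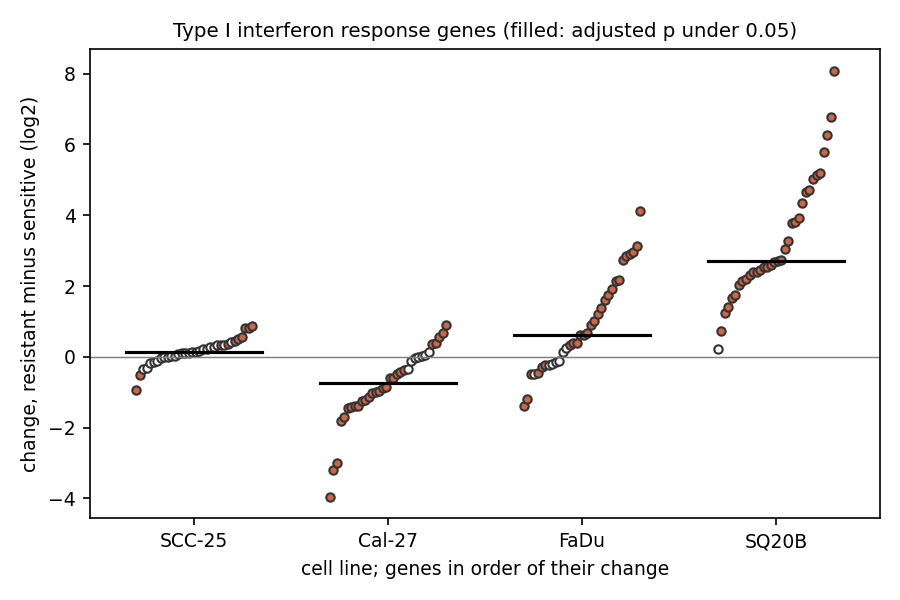
Change of the 34 measured type I interferon response genes in each line, resistant minus sensitive on the log2 scale (vertical axis), with genes ordered by their change within each line (horizontal axis), filled points for called genes and a bar at the median. The medians were 0.14 in SCC-25, -0.73 in Cal-27, 0.61 in FaDu and 2.70 in SQ20B.

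Some lists moved in both directions within a line and were called in none of the 4. EGFR family and ligand genes rose and fell in 4 and 4 of 10 cases in SCC-25, 3 and 2 in Cal-27, 3 and 4 in FaDu and 6 and 2 in SQ20B, with FaDu at 3 and 5 adjusted over the list alone. HBEGF, which encodes an EGFR ligand, fell by 1.33 ± 0.13 in SCC-25 and fell by 0.54 ± 0.10 in FaDu, and rose by 2.74 ± 0.13 in Cal-27 and 2.75 ± 0.10 in SQ20B. TGFA, another EGFR ligand on the list, was called lower in all 4 lines. It stood at -0.633 in SCC-25, -0.289 in Cal-27, -0.609 in FaDu and -1.08 in SQ20B, and its Cal-27 call was lost under 6 alternatives. Camera adjusted p for that list was 0.918, 0.537, 0.723 and 0.144. Other receptor tyrosine kinase genes and ligands rose and fell in 5 and 8 of 23 cases in SCC-25, 8 and 8 in Cal-27, 7 and 8 in FaDu and 9 and 7 in SQ20B. Adjusted over the list alone those counts were 5 and 11, 9 and 8, 8 and 9, and 9 and 7, and camera adjusted p was 0.138, 0.886, 0.723 and 0.835. IL-1 family and MyD88 genes rose and fell in 4 and 7 of 18 cases in SCC-25, 6 and 2 in Cal-27, 2 and 2 in FaDu and 8 and 4 in SQ20B. Adjusted over the list alone Cal-27 had 6 and 3, and camera adjusted p was 0.405, 0.184, 0.723 and 0.251.

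NRF2 targets rose and fell in 5 and 6 of 26 cases in SCC-25, 8 and 7 in Cal-27, 5 and 12 in FaDu and 5 and 10 in SQ20B, with 8 and 8 in Cal-27 adjusted over the list alone. ALDH3A1, an aldehyde dehydrogenase, rose by 1.56 ± 0.18 in SCC-25, 2.01 ± 0.18 in Cal-27, 1.49 ± 0.11 in FaDu and 0.84 ± 0.11 in SQ20B. GPX2, on the same list, was called lower in all 4 lines, at -0.966, -1.45, -0.705 and -0.918 in that order. Camera adjusted p was 0.587, 0.936, 0.0865 and 0.417. NADPH oxidase genes had 7 measured members, of which 3 rose and 2 fell in SCC-25, 1 and 1 in Cal-27, 3 and 0 in FaDu and 3 and 1 in SQ20B. NOXA1, an oxidase activator, rose by 0.89 ± 0.13 in Cal-27, 1.28 ± 0.17 in FaDu and 1.40 ± 0.17 in SQ20B and was not detected in SCC-25, and Cal-27 had 2 and 1 adjusted over the list alone. DUOX1, on the same list, stood at -0.66 in SCC-25 and -2.34 in Cal-27. Camera adjusted p was 0.807, 0.789, 0.192 and 0.45. BCL2 family genes rose and fell in 3 and 4 of 17 cases in SCC-25, 3 and 3 in Cal-27, 2 and 5 in FaDu and 5 and 5 in SQ20B. HRK, a pro-apoptotic member, rose by 1.33 ± 0.15 in SCC-25, 1.98 ± 0.14 in FaDu and 1.57 ± 0.14 in SQ20B and was not detected in Cal-27. PMAIP1, another member, was called at -1.25 in SCC-25 and at 0.56 in Cal-27. Camera adjusted p was 0.557, 0.779, 0.614 and 0.899. Of 11 leukocyte, endothelial and melanocyte markers, 2 rose in each line, and 2 fell in Cal-27, 2 in FaDu and 0 in SCC-25 and SQ20B, with camera adjusted p of 0.528, 0.507, 0.723 and 0.668. The IL-6 list was called in Cal-27, as given above, and not in the other lines. There it had 3 higher and 3 lower of 15 in SCC-25, 6 and 2 in FaDu and 3 and 0 in SQ20B, with 6 and 3 in SCC-25 adjusted over the list alone (camera adjusted p = 0.587, 0.489 and 0.251). It is not independent evidence.

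**Figure D3:**
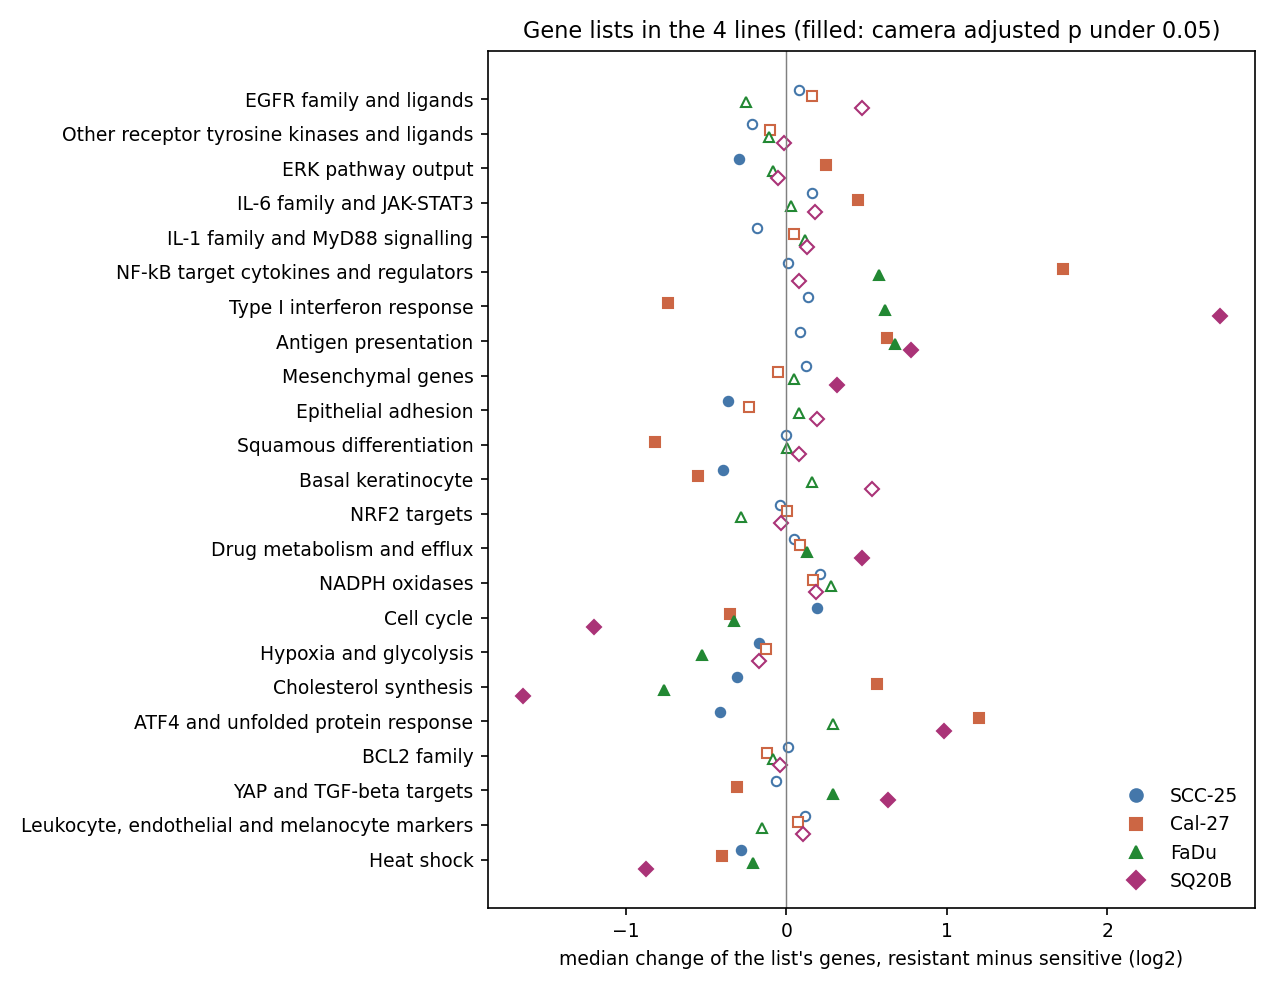
Median log2 change of the measured genes of each of the 23 lists (horizontal axis), resistant minus sensitive, with 1 symbol per cell line and filled symbols where camera's adjusted p was under 0.05. Heat shock genes were called lower in all 4 lines, and cell cycle genes were called higher in SCC-25, with a median of 0.19, and lower in the other lines, with -1.20 in SQ20B, but with an estimated correlation heat shock was called in 0 lines and cell cycle in SQ20B alone.

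SCC-25 and Cal-27 changed many genes in opposite directions, though 55.7% of the genes called in both had the same direction. GDF15 fell in SCC-25, where resistant cells were at least 1.46-fold lower, and rose by 6.37 ± 0.14 in Cal-27 (adjusted p = 2.58e-10 for the difference). PPP2R2B, a phosphatase subunit, rose by 3.05 ± 0.12 in SCC-25 and fell by 3.10 ± 0.12 in Cal-27, and MAOA, monoamine oxidase A, rose by 2.31 ± 0.13 and was at least 6.14-fold lower. FEZ1 fell by 2.21 ± 0.15 in SCC-25 and rose by 3.47 ± 0.15 in Cal-27. The ATF4 and unfolded protein response list differed by a median of -1.72 (camera adjusted p = 3.39e-13, and 0.0845 with an estimated correlation). ERK pathway output differed by -0.81 and cholesterol synthesis by -0.76, and cell cycle genes by 0.60, and with an estimated correlation their adjusted p was 0.0896, 0.0896 and 0.0845. NF-kB targets differed by -1.52 and interferon-response genes by 0.84, and both kept their call with an estimated correlation, at adjusted p = 0.0234 and 0.00673. The interaction was called for 4726 of 14077 genes. In both lines, 855 genes were called with opposite signs, 516 were called higher and 560 were called lower.

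FaDu and SQ20B were more alike, and the size of the change differed for interferon, cell cycle and cholesterol synthesis genes. The interferon-response list differed by a median of -2.44 (camera adjusted p = 2.63e-29, and 2.24e-05 with an estimated correlation). Cell cycle genes differed by 0.91 (camera adjusted p = 7.99e-17, and 0.00206 with an estimated correlation), cholesterol synthesis genes by 0.92 and ATF4 and unfolded protein response genes by -0.79. TGM2, a transglutaminase, rose by 3.19 ± 0.07 in FaDu and fell by 2.24 ± 0.07 in SQ20B, and VGLL1, a TEAD cofactor, rose by 3.53 ± 0.11 and fell by 1.76 ± 0.11. CKB, a creatine kinase, rose by 1.26 ± 0.13 and fell by 3.31 ± 0.13. ACKR3, a chemokine receptor, fell by 0.62 ± 0.10 in FaDu and rose by 3.94 ± 0.10 in SQ20B. The interaction was called for 4707 genes, and 461 genes were called in both lines with opposite signs.

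Some genes changed alike in all 4 lines. CFB rose by 1.16 ± 0.12 in SCC-25, 2.84 ± 0.12 in Cal-27, 4.44 ± 0.11 in FaDu and 2.95 ± 0.11 in SQ20B. In sensitive SQ20B cells CFB lay at 4.8 to 5.14, near background, so the size of that rise depends on the background correction. LCN2 rose by 1.19 to 5.17 and CYP1B1 by 1.63 to 4.37. CYBRD1, an iron reductase, rose by 0.68 to 3.39 and SASH1 by 1.51 to 2.69. FGFBP1 changed by -1.47 ± 0.08, -1.22 ± 0.08, -1.56 ± 0.12 and -3.59 ± 0.12 in the same order of lines, SFN, the cell cycle regulator stratifin, by -1.06 ± 0.08, -1.73 ± 0.08, -1.83 ± 0.08 and -1.34 ± 0.08, and CA2, MMP13 and IL7R were also lower in each line. In all, 229 genes were higher and 180 lower in all 4 lines, where independent lists of these lengths would share 20.8 and 20. The lines did not change independently, as FaDu and SQ20B correlated at r = 0.534. Part of the excess can thus come from the likeness of some lines, and it does not measure a change common to all 4. In 203 other genes called in all 4 lines, SCC-25 went against the rest. At least a 2-fold change in each line was left for 9 higher genes (CFB, CYP1B1, IL6, LCN2, MUC1, PLAG1, SASH1, TIMP2 and WFDC2) and 3 lower (FGFBP1, SFN and TM4SF19). MUC1, PLAG1 and TIMP2 were named here after their values were seen.

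The mean change over the 4 lines was called for 0 genes by limma, and 2075 genes had an unadjusted p under 0.05. The lowest adjusted p was 0.282, shared by many genes, among them PLAG1, a zinc finger transcription factor, at a mean change of 1.28 ± 0.12. Here the 4 lines are the replicates, so the test asks more than the count of shared calls. Over all tested genes, the changes of FaDu and SQ20B correlated at r = 0.534 and those of SCC-25 and Cal-27 at r = 0.0539. Between tables r was 0.265 for Cal-27 and FaDu, 0.227 for Cal-27 and SQ20B, 0.167 for SCC-25 and FaDu and 0.0727 for SCC-25 and SQ20B. These 6 correlations are across genes, which are not independent replicates. Of 4233 genes called in both FaDu and SQ20B, 89.1% had the same direction, against 55.7% of 1931 genes called in both SCC-25 and Cal-27.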

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

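Differences between lines of the same table were picked out for a closer look. The resistant change differed between SCC-25 and Cal-27 for 4726 genes and between FaDu and SQ20B for 4707. The count by kind of relabelling was chosen only after the result was seen. In 100 relabellings of the arrays within SCC-25 and Cal-27, 1, the real one, gave as many as 4726, and the highest other gave 1970. A relabelling that mixes a line also removes that line's change. The low counts thus show that sensitive and resistant arrays differ, and do not test whether the 2 lines changed differently. The relabellings were drawn with repeats. Over all 200 distinct relabellings 2 gave as many, the other being the exchange of all arrays of 1 line, with 5114. For FaDu and SQ20B, 6 of 100, the real one included, gave as many as 4707, and the highest other gave 8247. That count does not settle whether chance is excluded, since it holds relabellings that keep the real division of a line and so its change. Over all 200 distinct relabellings 8 gave as many: the real one, the exchange of all arrays of 1 line, with 8247, and 6 of the 18 that divide only SQ20B as it is, with up to 4915. Where both lines were mixed, 0 of 162 gave as many, and the highest called 0 genes. The change of SQ20B alone thus reached the count of 4707 with the FaDu arrays mixed. An earlier version of the drawn test left out the exchange of a whole line and gave 3 of 100, with a highest other of 4915.

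Among genes called in opposite directions, large differences between SCC-25 and Cal-27 were -7.10 for GDF15, 6.15 for PPP2R2B, -5.68 for FEZ1, -5.68 for CCL20 and 5.52 for MAOA. GDF15 in resistant SCC-25 cells and MAOA in resistant Cal-27 cells were not detected, so the size of these 2 differences depends on the background and their place among the others is not read. Between FaDu and SQ20B the largest were 5.42 for TGM2, 5.29 for VGLL1, -4.96 for IFI44, -4.56 for ACKR3 and 4.56 for CKB. The FaDu value of IFI44 lost its call under 3 alternatives. Lists called in opposite directions in SCC-25 and Cal-27 differed by a median of -0.815 for ERK pathway output, 0.601 for cell cycle, -0.763 for cholesterol synthesis and -1.72 for ATF4 and unfolded protein response. None of these list differences was called with an estimated correlation (camera adjusted p = 0.0896, 0.0845, 0.0896 and 0.0845).

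Signal was also present in probes without a gene name in the annotation used here. Of 7518 such probes detected on at least 3 arrays, 87 in SCC-25, 174 in Cal-27, 166 in FaDu and 571 in SQ20B were called with at least a 2-fold change. What they measure is not given in the sources used here. With 3 arrays per group, no array was tested for lying far from its group.

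For CYP1A1 and CYP1B1, higher in resistant Cal-27, FaDu and SQ20B cells, the tests of a probe fault and of normalization were chosen only after the result was seen. Activity of the aryl hydrocarbon receptor, AHR, predicted a rise of other AHR targets, of which 8 were measured, in at least 3 lines. The list of AHR targets was higher with limma's camera p under 0.05 in 0 lines. Of the 8 genes, 1 rose and 1 fell in SCC-25, 4 and 1 in Cal-27, 1 and 0 in FaDu and 3 and 2 in SQ20B, with medians of 0.0567, 0.247, 0.068 and 0.0666. The prediction was thus not met. AHR activity still stays open, since members went both ways and the list left out the AHR targets already seen to change. Of those, ALDH3A1 rose in all 4 lines, and UGT1A6 rose by 1.01 in SCC-25, 2.30 in FaDu and 1.29 in SQ20B and fell by 0.64 in Cal-27. These 2 genes were picked after their values were seen, so they are not evidence for AHR activity. A fault of the CYP1A1 probe also stays open: CYP1B1 was called higher through another probe in all 3 lines, but in SCC-25 CYP1B1 rose by 2.35 while CYP1A1 stood at 0.18, so 1 gene does not test the probe of the other. Background correction and normalization are excluded as the whole cause, since the lowest change of CYP1A1 over 5 alternatives was 2.32.

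For the interferon-response genes, lower in Cal-27 and higher in FaDu and SQ20B, the test of leukocytes was chosen only after the result was seen. Leukocytes in the resistant SQ20B culture are not seen in LYZ, CD53 and ITGAM, whose largest change was 0.11, with limma's adjusted p = 0.536, 0.529 and 0.834. Of the 11 measured leukocyte, endothelial and melanocyte markers, 2 were called higher and 0 lower in SQ20B. That list was not called (camera adjusted p = 0.668), and its other members were not part of the leukocyte test. Background correction and normalization are excluded as the whole cause, since the list kept its call and direction in 15 of 15 fits of 3 lines by 5 alternatives. Interferon transcripts made by the SQ20B cells stay open. They predicted an interferon gene detected on 3 resistant arrays and called higher, and whether IFNE met this depends on the adjustment. Its brightest probe, detected on 3 resistant arrays and 1 sensitive array, stood at 0.37. Limma's adjusted p was 0.0405 over the tested genes and 0.0524 over all detected probes. Other IFNE probes stood at 0.212 and -0.138 (adjusted p = 0.241 and 0.668 over all detected probes). The IFNB1 probe, detected on 2 resistant arrays and 0 sensitive arrays, stood at 0.443 and was detected on too few arrays to be tested. Interferon protein and added interferon were not measured.

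For SQ20B as the line with the most changed genes, the test against the other lines was chosen only after the result was seen. The values count against a resistant culture of another line of this series, since resistant SQ20B cells correlated at 0.943 with sensitive SQ20B cells and at 0.895 with the next sensitive line. The margin is small beside the likeness of different lines, as sensitive cells of 2 lines correlated at up to 0.937 and resistant SQ20B with resistant FaDu cells at 0.915. A deviating array is excluded as the whole cause, since at least 1957 genes changed at least 2-fold whichever SQ20B array was left out, against 813 in the next line. Background correction and normalization are excluded as the whole cause, since SQ20B had the highest such count under 5 of 5 alternatives. A biological cause was not tested.

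Within a line, the 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. In SCC-25 1 split, the real one, gave as many as 4348 genes, and the highest other gave 0. For Cal-27 it was 1, with 4765 genes against 0, for FaDu 1, with 5762 against 1, and for SQ20B 1, with 7640 against 1. For lists the splits with as many calls were also 1 in each line, with 8 against 6 in SCC-25, 12 against 11 in Cal-27, 9 against 5 in FaDu and 9 against 8 in SQ20B. Other splits thus called nearly as many lists by camera with its preset correlation in 3 of these lines, which limits what a count of called lists can show. For genes changed alike in all 4 lines, 1 of 100 relabellings, the real one, gave as many as 409, and the highest other gave 0. A mixed line calls almost no genes, so the other counts were bound to lie near 0. These relabellings therefore exclude nothing, and do not test whether the lines share more genes than lines that change independently. For the mean change over the lines, 8 of 8 sign patterns gave as many as 0, which are too few for a share under 0.05.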

How the results depend on the processing

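For 463 named gene values, each under the settings that apply to it, 7748 results kept their side of the threshold and direction, 116 lost their call and 4 reversed, while for 92 list values 1611 stayed the same, 38 lost and 7 gained a call. Apart from the genes taken whatever their call, named genes were chosen for large called changes in these data. Their stability therefore does not speak for the other calls. Of 38 list calls, 36 held under every setting other than the estimated correlation, and 15 were called with it. With an estimated correlation in camera, 0 lists were called in SCC-25, 4 in Cal-27 and 5 in FaDu. With no background correction, at least 2-fold changes numbered 185 in SCC-25, 317 in Cal-27, 299 in FaDu, 910 in SQ20B, 567 for SCC-25 minus Cal-27 and 546 for FaDu minus SQ20B. With normexp and an offset of 50 they numbered 268, 437, 404, 1176, 748 and 735. Both keep more background in the signal, which makes folds smaller. With the mean of a gene's probes, HLA-DRA in SCC-25 turned to 0.0997, EGFR in SCC-25 to -0.223, ERBB3 in Cal-27 to -0.120 and ERBB3 in SQ20B to -0.110, as their probes disagree; for EGFR in SCC-25 adjusted p ranged from 5.6e-05 to 0.0304 over 17 alternatives. Genes changed alike in each line numbered 12 with at least a 2-fold change, 1558 in the 3 lines other than SCC-25 and 898 in the 3 lines other than Cal-27. On genes detected on every array of both lines, r was 0.19 for SCC-25 and FaDu, 0.313 for Cal-27 and FaDu, 0.303 for Cal-27 and SQ20B and 0.582 for FaDu and SQ20B. With median scaling, SCC-25 had 2449 genes higher and 1898 lower, so its even balance depends on the normalization. The cause was not tested.

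With each array left out in turn, calls ranged over 3707 to 4058 in SCC-25, 3928 to 4158 in Cal-27, 5168 to 5446 in FaDu and 7079 to 7238 in SQ20B. At least 2-fold changes ranged over 546 to 579, 796 to 823, 819 to 858 and 1957 to 2030, and lists over 6 to 9, 12 to 12, 9 to 9 and 9 to 9. For SCC-25 minus Cal-27 the ranges were 4171 to 4846 and 1329 to 1402, for FaDu minus SQ20B 4160 to 4464 and 1308 to 1352, and for genes shared by the lines 329 to 440. The mean change stayed at 0.

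With the replicate number as a replicate block, 4165 genes were called in SCC-25, 4569 in Cal-27, 5664 in FaDu and 7570 in SQ20B. The pairing check gave correlations of -0.069 to 0.07 over 12 pairs, 0 of them over 0.1, so the numbers do not pair the samples, and own numbers correlated best for 0, 2, 1 and 2 samples in SCC-25, Cal-27, FaDu and SQ20B. The slide as a block was not run, because the columns name no slide.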

Other observations

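Genes called in all 4 lines fell into 8 patterns of direction. The most frequent, with 409 genes, was the same direction everywhere. In 203 genes SCC-25 went against the other 3 lines, and in 99 genes Cal-27 did. In 67 genes SCC-25 and Cal-27 together went against FaDu and SQ20B.

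CCNG2, CDKN1B, IRS2 and ERBB3, known targets of FOXO transcription factors, rose in all 4 lines, which led to the hypothesis that FOXO activity was higher in resistant cells. They were noticed after their values were seen, and the rise of ERBB3 depends on the probe in Cal-27 and SQ20B. The prediction, written before the test, was that a list of FOXO targets not yet looked at would be higher in at least 3 lines. The list had 14 genes, 13 of them measured and 0 of them in the 23 lists. It was higher with camera p under 0.05 in 3 lines, at p = 0.00654 in Cal-27, 8.42e-06 in FaDu and 4.99e-06 in SQ20B, and 0.0323, 0.00151 and 0.0013 with an estimated correlation. In SCC-25 p was 0.862, so the list does not account for genes higher in all 4 lines. Of the 13 genes, 2 rose and 3 fell in SCC-25, 7 and 2 in Cal-27, 10 and 1 in FaDu and 11 and 1 in SQ20B. TXNIP rose by 3.05 in FaDu and 2.76 in SQ20B and fell by 0.31 in Cal-27, and TNFSF10, a death ligand, rose by 1.08 in Cal-27, 1.81 in FaDu and 2.29 in SQ20B. FOXO activity stays a hypothesis, since transcripts of targets also answer to other factors, and FOXO protein was not measured. Whether erlotinib was present in the last 48 h is not given, so an effect of the drug cannot be told apart from resistance. The changes of FaDu and SQ20B also correlated at r = 0.534, so the lines do not count as independent tests. TNFSF10 is also induced by interferon.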
